A study of Mus musculus with 2 samples.

How the data were processed

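The study holds 2 samples of mouse femur RNA, 1 from sham-operated and 1 from ovariectomised (OVX) animals, each pooled from 4 mice per the series description. Per the labels' protocols, fresh femurs with marrow and bone were homogenised, RNA was extracted with a kit that keeps small RNA, and it was labelled with Cy3; the labels name an amplification kit for cRNA, which does not describe how a miRNA array is usually labelled, and this was left as it stands. The samples were on 1 slide with 1 scan date, so slide and scan do not separate the groups.

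The deposited scanner files were made with Agilent Feature Extraction; version 10.7.1.1 stands in the file headers and version 11.0.1.1 in the submitters' processing notes. They give intensities per spot: per the file headers, the processed intensity is the spot brightness after background subtraction and is not normalized between arrays, and the mean and local background intensities are uncorrected. Each array has 58594 spots, 56430 of them for miRNAs, with 4415 probes for 1881 mouse miRNAs, 1 to 4 probes per miRNA and a median of 15 usable spots per probe. The files use mouse build mm9; coordinates are the probe matches they list, some of which span 1 base less than the probe. Gene symbols and neighbouring genes come from a RefSeq table of assembly GRCm38, from which no coordinate was taken; 73 of the 94 named miRNAs matched an entry by name.

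The deposited value table holds log2 values made by the authors, with the normalization not given in the sources used here. Its columns have medians of -3.18 (sham) and -3.32 (OVX), their floors, and over the 291 highest rows the sorted columns are equal to 4 decimals, which is what quantile normalization gives. Its row names do not go with its values: under the names as printed, the Spearman correlation with the array's gene-level signal over all rows was 0.04 for sham and 0.06 for OVX, and with the names moved by 1 row it was 0.99 for each. Among detected miRNAs the moved names gave 0.987 and 0.996 with the sum of the miRNA's probe signals, and as printed -0.02 and 0.02. The table was therefore used only as an alternative, with names moved by 1 row. Its scale is log2 and its centring follows the normalization.

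Agilent's gene-level signal, also deposited in the scanner files, did not always match its own probes. For 102 of the 291 miRNAs called detected on the sham array and 99 of 372 on the OVX array it departed from the sum of the probes' total signals by more than 0.05 on the log2 scale, with a median departure of 1.70 and 2.02. Their brightest probe was at or below 96.2 on the sham array and 145.6 on the OVX array, 34 and 15 of them were present on both arrays, and in the value table their order followed the probes (Spearman 0.79 and 0.89) more than the gene-level signal (0.16 and 0.04). The cause was not tested. Agilent's effective feature size, which enters this signal, was 0.6 on the sham array, a default, and 0.781 on the OVX array. The gene-level signal was used only in an alternative.

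Spots with an outlier flag were left out (1554 on the sham array, 2.75%, and 1635 on the OVX array, 2.90%); no miRNA spot was saturated. Control spots were left out. The negative control spots had processed signals of 1.93 ± 2.81 (SD between 982 spots) on the sham array and 1.36 ± 2.86 (SD between 978 spots) on the OVX array. A probe was called well above background when over 50% of its spots were, and a miRNA present when at least 1 of its probes was. Processed signals were averaged per probe, converted to log2 and scaled by subtracting the array's 75th percentile over the 350 probes well above background on both arrays. A miRNA's level is the mean over those of its probes. The error is the spot SE, propagated from the spread between spots of a probe; it is technical and within the array, and the number of arrays limits the precision. Where a miRNA was present on 1 array only, a bound was computed from the scaled log2 values. A list's percentile places its median among 10000 random lists of the same size drawn from 5 bins of mean level.

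No test was possible with 1 sample per group, so rules of size were used: at least 2-fold, with 1.5-fold as an alternative. The miRNAs named were fixed by rule before the data were examined: the 10 highest and the 10 lowest differences among miRNAs present on both arrays, at or above the median level and with all probes on the same side of 0; the 5 largest bounds in each direction; the 10 brightest; and from each of 20 fixed lists the 4 largest differences, or all members where at most 10 were measured. Alternatives were other scalings (75th percentile of all probes, median, quantile, none), normexp background correction with an offset of 50, other summaries per miRNA, other filters on dim probes, the value table, and, added after seeing the data, scaling to the control probes, removal of a trend with probe GC content, the gene-level signal without the departing miRNAs, and the value table with names as printed.

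The steps were tested on simulated spots for this comparison. With 59 miRNAs of known difference among 203 measured, all 20 at 2.5-fold and all 19 at 4.0-fold were called in the true direction at the 2-fold threshold, and none of the 20 at 1.5-fold or the 144 unchanged ones was. The scaling moved unchanged miRNAs by -0.28 on the log2 scale in that simulation. Both simulated arrays were drawn from the sham probe means with spot noise and a uniform gain of 2. They held no disagreement between probes beyond spot noise, no trend with GC and no variation between pools. The simulation therefore tests the calculation only. A list of 8 members shifted by 1 reached percentile 100.0, and 17 of 20 unshifted lists lay between percentiles 5 and 95. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for normexp.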

Results

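MicroRNA (miRNA) levels were compared in whole femurs, marrow and bone together, of 9-month-old female C57BL/6 mice after ovariectomy (OVX), the surgical removal of the ovaries that ends most estrogen production, and after a sham operation. The question was how miRNA levels in femur differ after loss of the ovaries. Each group was 1 pooled RNA sample from 4 mice, hybridised to 1 single-colour Agilent mouse miRNA array. With 1 array per group the difference has no replicate check, so no test was made and no p-value is given; "higher" and "lower" describe these 2 arrays. The errors printed are standard errors between spots of a probe within an array (spot SE) and hold no variation between mice. Differences are log2 OVX minus sham after each array was scaled to its 75th percentile, so they are relative to the other miRNAs on the array.

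Of the 1881 mouse miRNAs on the array, 202 were present on the sham array and 299 on the OVX array, where present means that a probe was well above background. Both arrays detected 197, and 1577 were well above background on neither. On the sham array 9.12% of the miRNA spots were well above background, and on the OVX array 13.42%. The OVX array was brighter by 1.01 on the log2 scale at the 75th percentile used for scaling, a factor of 2.02.

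Of the 197 miRNAs present on both arrays, 146 lay within 1.5-fold with this scaling; the 107 present on 1 array only are not among them. The differences had an SD of 0.52 and quartiles of -0.36 and 0.28. Probes of the same miRNA differed less, with an SD of 0.11 between them, and the median spot SE was 0.05. Of the 139 miRNAs with 2 or more measured probes, 128 had all probes on the same side of 0 and 11 had probes that disagreed. The probes of a miRNA differ by a median of 1 base in length and share the array and its labelling. Their SD and agreement therefore leave out any error common to the array or to base composition. With this scaling 4 miRNAs were at least 2-fold higher in OVX and 4 at least 2-fold lower. The counts were 97 and 0 without scaling, 40 and 0 with control-probe scaling and 0 and 0 with normexp background correction. Normexp adds an offset of 50 to each signal, which draws the log2 differences of dim miRNAs towards 0. Its counts are therefore not a stricter check of background. At 1.5-fold the counts were 22 and 29.

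**Figure D1:**
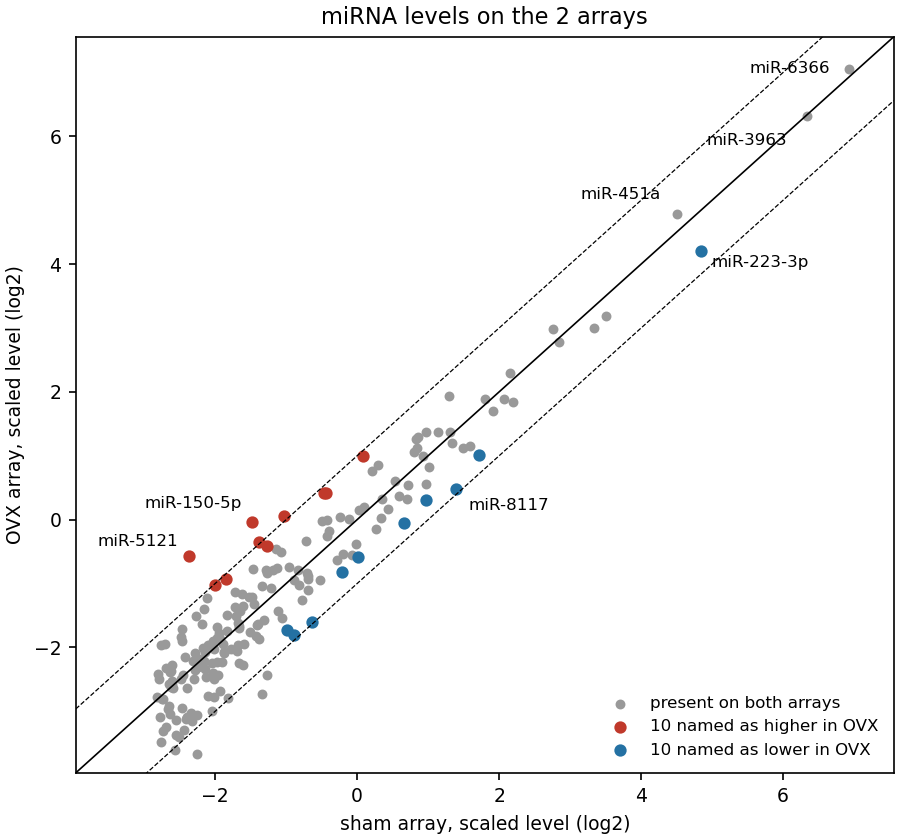
Scaled log2 levels of the 197 miRNAs present on both arrays, sham on the x axis and OVX on the y axis, 1 point per miRNA. The solid line marks equal levels and the dashed lines a 2-fold difference; the red and blue points are the 10 miRNAs named as higher and the 10 named as lower in OVX, from miR-5121 at 1.79 to miR-7047-5p at -0.97.

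The 10 miRNAs with the brightest probes included 1 of red cells and 1 of granulocytes; brightness depends on the probe and does not rank abundance. miR-451a, the red-cell miRNA made from the same transcript as miR-144, had a level of 4.51 in sham and 4.78 in OVX, a difference of 0.28 (spot SE 0.03). miR-223-3p, the abundant miRNA of granulocytes, had a level of 4.84 in sham and 4.21 in OVX, a difference of -0.63 (spot SE 0.02), or 0.644-fold, with both of its probes lower, but it was at -0.25 in the value table, 0.38 without scaling and 0.0013 with control-probe scaling. miR-6366 and miR-3963 had differences of 0.13 and -0.01. The remaining 6 of the 10 differed by -0.31 (miR-466i-5p), -0.34 (miR-15b-5p), 0.23 (miR-5100), -0.06 (miR-494-3p), 0.14 (miR-3968) and -0.35 (miR-574-5p). Without scaling miR-466i-5p (0.70), miR-15b-5p (0.68), miR-574-5p (0.66), miR-494-3p (0.96) and also miR-3963 were above 0, and with median scaling miR-6366 (-0.06) and miR-3968 (-0.04) were below. In the files, which use mouse build mm9, the miR-223-3p probes match chromosome X from 93438225 to 93438244 and the miR-451a probes match chromosome 11 from 77886689 to 77886709.

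Among miRNAs of at least median level whose probes all lay on the same side of 0, miR-5121, miR-150-5p, miR-142a-5p and miR-26b-5p were more than 2-fold higher in OVX. A miRNA with 1 measured probe meets the same-side rule by itself. miR-5121 was 3.47-fold higher (log2 1.79, spot SE 0.05). The RefSeq table used here (assembly GRCm38) places its gene inside Rpl13a, a ribosomal protein gene. miR-150-5p, which is abundant in mature B and T cells, was 2.70-fold higher (log2 1.43, spot SE 0.14), measured by 1 probe that matches chromosome 7 from 52377139 to 52377153. miR-142a-5p, a miRNA of blood cells, was 2.11-fold higher (log2 1.08, spot SE 0.04), with a chromosome 11 match from 87756870 to 87756887. miR-26b-5p, whose gene lies inside Ctdsp1, was 2.05-fold higher (log2 1.04, spot SE 0.06), with a match on chromosome 1 from 74440900 to 74440918. With normexp, whose offset draws the differences of dim miRNAs towards 0, none of the 4 reached 2-fold (0.65, 0.76, 0.63 and 0.47 in the order above). miR-142a-5p and miR-26b-5p also fell short with median scaling (0.90 and 0.85), the value table (0.97 and 0.90) and the sum of probes (0.998 and 0.93). They fell short with GC correction as well (0.81 and 0.81), as did miR-26b-5p with quantile normalization (0.96) and its brightest probe (0.95). All 10 named as higher passed 2-fold with the 75th percentile of all probes, without scaling and with control-probe scaling. The other 6 of these 10 were miR-144-5p (0.97), miR-574-3p (0.92), miR-21a-5p (0.90), miR-29b-3p (0.89), miR-376b-3p (0.86) and miR-144-3p (0.85). Differences fell as probe GC content rose (Spearman's rho -0.32 across the 197 miRNAs). miR-142a-5p, miR-26b-5p, miR-144-5p, miR-21a-5p, miR-29b-3p and miR-144-3p had probes under 40% GC. With GC correction, added after seeing the data, all 10 stayed above 0. miR-144-5p was then at 0.68 and miR-144-3p at 0.57, and only miR-574-3p rose, to 0.95. miR-21a-5p lies at the end of Vmp1 and is often raised in inflamed or growing tissue; its probes match chromosome 11 from 86397588 to 86397607.

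The largest lower values under the same rule stayed within 2-fold with this scaling, but miR-7047-5p (-1.15), miR-6937-5p (-1.10) and miR-8117 (-1.10) passed it with median scaling. miR-7047-5p and miR-6937-5p also passed it with quantile normalization and the value table, and miR-7047-5p and miR-8117 with the sum of probes. miR-7047-5p differed by -0.97 (spot SE 0.04), miR-6937-5p by -0.92 (spot SE 0.06, 1 probe) and miR-8117 by -0.91 (spot SE 0.03). miR-486a-5p, found in red cells and muscle, was 0.612-fold (log2 -0.71, spot SE 0.03), and its level went from 0.66 in sham to -0.05 in OVX. The other 6 were miR-677-3p (-0.74), miR-1949 (-0.71), miR-7042-5p (-0.65), miR-223-3p (-0.63), miR-6769b-5p (-0.61) and miR-3473g (-0.59). miR-7047-5p, miR-6937-5p, miR-486a-5p, miR-7042-5p, miR-6769b-5p and miR-3473g had probes above 60% GC. With GC correction all 10 named as lower stayed below 0, with miR-486a-5p at -0.49 and miR-6769b-5p at -0.44. miR-1949 (-0.85) and miR-223-3p (-0.80) were then lower than as reported. The 4 miRNAs at least 2-fold lower were all below the median level and so outside that rule; picked out after their values were seen, they were miR-7686-5p (-1.41), miR-6997-5p (-1.40), miR-6360 (-1.15) and miR-664-5p (-1.04). The 10 named as lower stayed below 0 under each planned setting except no scaling between the arrays, where all 10 were above 0; after scaling to the control probes, an alternative added after seeing the data, 7 of the 10 were below 0. The 10 named as higher stayed above 0 under each planned setting except Agilent's gene-level signal, where miR-144-5p (-1.29) and miR-29b-3p (-1.48) were below. In both, the gene-level signal departed from their own probes, and the other 8 stayed above 0 when such miRNAs were left out.

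**Figure D2:**
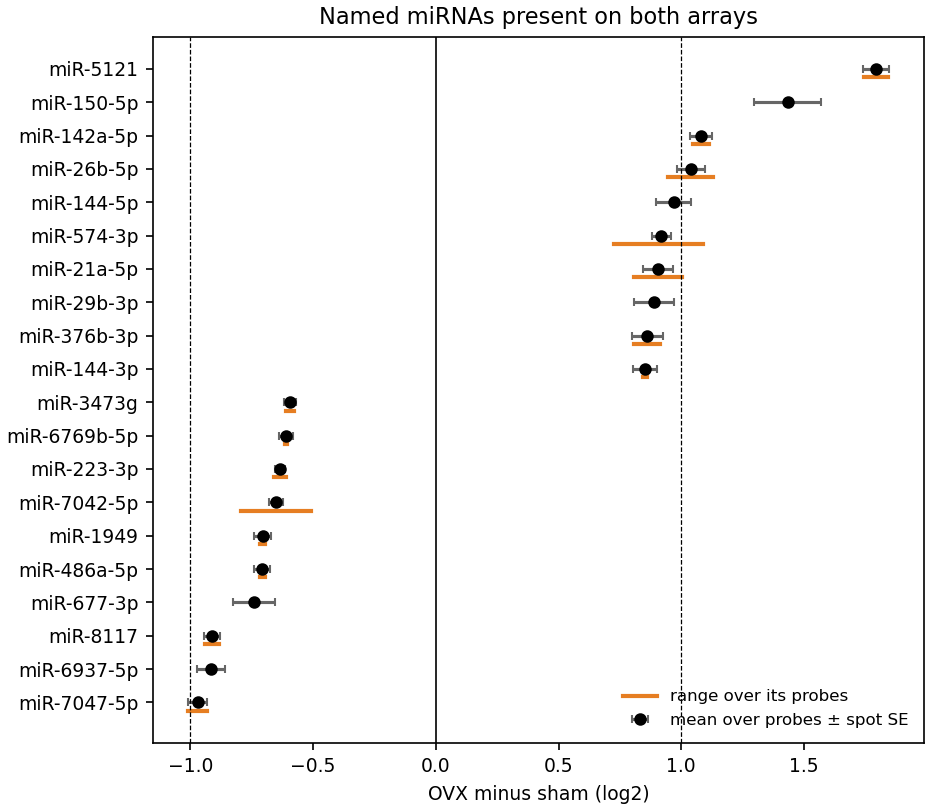
Log2 OVX minus sham (x axis) of the 10 miRNAs named as higher and the 10 named as lower, 1 row each. Points are means over probes with bars of 1 spot SE, orange lines span the miRNA's probes, and the dashed lines mark 2-fold; miR-5121, miR-150-5p, miR-142a-5p and miR-26b-5p lie beyond 2-fold with this scaling and none of the lower ones does.

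A further 102 miRNAs were present on the OVX array only and 5 on the sham array only. These have bounds. The bright array's level was set against the lowest level among probes well above background on the other array. Where the dim probe's own level was higher, that was used instead. After scaling these lowest levels were -2.86 on the sham array and -3.76 on the OVX array. This gap raises the bounds of miRNAs present on the sham array only and lowers those of miRNAs present on the OVX array only. miR-146a-5p, a miRNA induced by inflammatory signalling, was at least 2.07-fold higher in OVX (4.18-fold without scaling and 3.22-fold with control-probe scaling). Only 1 of its 2 probes was present. The sham signal of that probe, 18.25, lay above the lowest counted as present, so the bound is the probe's own difference and carries no error. The next bounds in OVX were 1.62-fold for miR-467a-3p, 1.44-fold for miR-504-3p, 1.34-fold for miR-6918-5p and 1.28-fold for miR-466m-5p, and without scaling 3.27-fold, 2.90-fold, 2.70-fold and 2.59-fold. For 80 of the 102 the bound was at or below 1 and no fold is given; this was so for 21 with control-probe scaling and for 0 without scaling. The muscle miRNAs miR-133b-3p and miR-133a-3p, each with 1 of 2 probes present, were at least 2.80-fold and 2.04-fold higher in sham, but only 1.39-fold and 1.01-fold without scaling. miR-1897-3p was at least 2.21-fold higher in sham (log2 bound 0.13 without scaling), and the bounds of miR-3095-3p (1.86-fold) and miR-6944-5p (1.84-fold) were lost without scaling. All 5 were dim: the unscaled sham signal of miR-133b-3p was 26.75 against 16.34 in OVX, and that of miR-6944-5p was 18.27 against 20.06, where its spots were not well above background. miR-3095-3p gave the lowest signal counted as present on the sham array, 17.83, so its bound equals the gap between the lowest levels of the arrays.

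Of the lists of miRNAs fixed beforehand, 12 had at least 3 measured members. All 12 had medians below 0 when dim signals were floored and all miRNAs of a list were used. That sign follows from the floors: a miRNA at the floor on both arrays is given -0.90, also the median of all 1881. No list median lay below it. The median of all miRNAs was -0.04 as reported and -0.26 with normexp. It was 0.97 without scaling, 0.595 with control-probe scaling and -0.23 with median scaling. These settings add the same constant to every miRNA, so a list keeps its place relative to that median. Of the 4 red-cell miRNAs measured, miR-144-5p (0.97), miR-144-3p (0.85) and miR-451a (0.28) were above 0 and miR-486a-5p (-0.71) was below. Their median of 0.56 lay at percentile 97.9 among 10000 random lists of the same size and level, which describes these arrays and tests nothing about the conditions. It was 0.32 (percentile 89.2) after GC correction and 0.13 with the gene-level signal, or -0.02 relative to the median of all miRNAs. Over the 3 members left without departing gene-level signals it was 0.63, or 0.33 relative to the median of all. Myeloid miRNAs went both ways: miR-142a-5p (1.08), miR-142a-3p (0.63) and miR-130a-3p (0.25) were higher, and miR-223-3p (-0.63), miR-24-3p (-0.37), miR-27a-3p (-0.34) and miR-23a-3p (-0.33), the last 3 made from a single cluster or its paralog, were lower. Their median was -0.33 (percentile 9.6), and it was 0.68 without scaling and 0.30 with control-probe scaling. Relative to the median of all miRNAs it was -0.29 in each of these settings, which differ by a constant only. It was -0.04 with normexp, -0.13 in the value table and 0.56 with dim signals floored. The mean of the myeloid miRNAs was 0.04 as reported, so median and mean differ in sign. Lymphoid miRNAs had a median of 0.22 (percentile 80.0), but -0.26 over the 8 in the value table, with miR-150-5p (1.43), miR-29b-3p (0.89) and miR-342-3p (0.22) above 0 and miR-181b-5p (-0.36) and miR-181a-5p (-0.21) below, and the endothelial miR-126a-3p was 1.70-fold (log2 0.77).

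miRNAs reported to act in bone cells went both ways, with small list medians. Of the 9 measured that favour osteoblasts, 6 were above 0 and 3 below, with a median of 0.13 (percentile 78.3) that became -0.06 when arrays were scaled to their median. The miR-29 family, whose targets include collagens and osteoblast inhibitors, was above 0 in all 3 measured members. These were miR-29c-3p (0.90), miR-29b-3p (0.89) and miR-29a-3p (0.39). With a gene-level signal that departed from its probes, miR-29b-3p was at -1.48. In the same list miR-2861 (-0.71) and miR-378a-3p (-0.69) were lower, and after GC correction they were at -0.19 and -0.73. Of the 12 measured that restrain osteoblasts, 7 were below 0, led by miR-221-3p (-0.84) and miR-103-3p (-0.42), and 5 above, led by miR-30e-5p (0.50). The median was -0.23 (percentile 9.2), and 0.78 without scaling and 0.40 with control-probe scaling. Relative to the median of all miRNAs it was -0.19 as reported and -0.18 in the value table. It was -0.02 with normexp and 0.00 with dim signals floored. The osteoclast list holds miRNAs reported to act in either direction, so its signs show no direction of osteoclast formation. Of the 7 measured osteoclast miRNAs, 6 were above 0, from miR-148a-3p (0.04) to miR-21a-5p (0.90), and miR-223-3p (-0.63) was below. Their median was 0.08 (percentile 77.1), and -0.11 when arrays were scaled to their median. miR-29b-3p (0.89) is counted in this list, in the list that favours osteoblasts and in the lymphoid list. Other lists share members too, so their percentiles are not separate results. The list that restrains osteoblasts shares miR-23a-3p, miR-24-3p and miR-27a-3p with the myeloid list. It shares miR-103-3p, miR-30a-5p and miR-30d-5p with the fat-cell list. The osteoclast list shares miR-21a-5p and miR-34a-5p with the stress and inflammation list. Fat-cell miRNAs had a median of -0.27 (percentile 13.6), and 0.74 without scaling and 0.36 with control-probe scaling. Relative to the median of all miRNAs it was -0.23 as reported and -0.34 in the value table. It was -0.09 with normexp and 0.27 with dim signals floored. Of the 7 measured, 5 were below 0, including miR-378a-3p (-0.69), miR-107-3p (-0.43) and miR-103-3p (-0.42).

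Of the 8 measured members of the fixed list of rodent repeat miRNAs, drawn up for the cluster in Sfmbt2, 7 were above 0, led by miR-466f-3p (0.85), miR-466g (0.70) and miR-466i-3p (0.69), while the bright miR-466i-5p (-0.31) was below. The list's median of 0.51 lay at percentile 99.3, and it was 0.07 with normexp, or 0.32 relative to the median of all miRNAs. The RefSeq table places only the 3 miR-669 members in Sfmbt2, puts miR-466i in Cdk13 and miR-467f in Fxr2, and was not matched to miR-466f or miR-466g. These 3, miR-669f-3p (0.55), miR-669l-5p (0.36) and miR-669e-5p (0.28), were at -0.07, -0.26 and -0.25 with normexp, where the median of all miRNAs was -0.26. With a gene-level signal that departed from its probes, miR-669e-5p was at -0.60. The 3 measured stress and inflammation miRNAs, miR-21a-5p (0.90), miR-34a-5p (0.39) and miR-212-3p (0.22), were all above 0 (median 0.39, percentile 93.6). With normexp the median was 0.01, or 0.27 relative to the median of all miRNAs. However, miR-34a-5p was at -0.27 with normexp and at -0.26 with dim signals floored, where the median of all was -0.90. With a gene-level signal that departed from its probes, miR-34a-5p was at -2.79. miR-212-3p was at -0.03 in the value table.

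The miRNAs reported to target the estrogen receptor gene Esr1 had a median of 0.13 (percentile 74.0) and a mean of -0.02, opposite in sign, from miR-221-3p (-0.84) to miR-19b-3p (0.43), and the median was -0.05 when arrays were scaled to their median and -0.02 with normexp. The proliferation-linked miR-17 cluster and its paralogs had a median of 0.14 (percentile 81.3; -0.04 with median scaling), with miR-19a-3p (0.57) and miR-19b-3p (0.43) above 0 and miR-17-3p (-0.58) and miR-92a-3p (-0.40) below. The let-7 family had a median of 0.06 (percentile 64.6), and it was -0.13 with median scaling and -0.17 after GC correction. In this family let-7f-5p (0.56) and let-7g-5p (0.55) were highest and let-7b-5p (-0.22) lowest. After GC correction let-7g-5p (0.33) was highest and let-7d-5p (-0.35) lowest. Lists with under 3 measured members have values only: miR-10a-5p (-0.48) and miR-125b-5p (0.34) for mesenchymal cells, miR-140-3p (-0.49) and miR-140-5p (0.17) for cartilage, and miR-376b-3p (0.86) and miR-494-3p (-0.06) for the imprinted Dlk1-Dio3 cluster. Of these, miR-10a-5p (0.54), miR-140-3p (0.52) and miR-494-3p (0.96) were above 0 without scaling. miR-140-5p was at -0.02 with median scaling and -0.21 with normexp. miR-125b-5p was at -0.09 with normexp, -0.28 with dim signals floored and -3.70 with a gene-level signal that departed from its probes. miR-494-3p was also above 0 with the 75th percentile of all probes (0.10), quantile normalization (0.13), normexp (0.16) and the gene-level signal (0.29).

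Markers of other tissues were at or near background. No member of the skeletal muscle list was present on both arrays. miR-486a-5p, found in red cells and muscle and not in that list, was present on both. miR-1a-3p had a processed signal of 7.09 in sham and 11.19 in OVX, below the lowest signals counted as present, 17.83 and 19.29. No member of the neural, liver and epithelial list or of the miR-183 cluster was present on both arrays, and only miR-192-5p of the former was present on the OVX array. Of the miR-338 cluster only miR-338-3p was present, on the OVX array alone, with a bound below 1 as scaled here and of 1.65-fold without scaling.

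**Figure D3:**
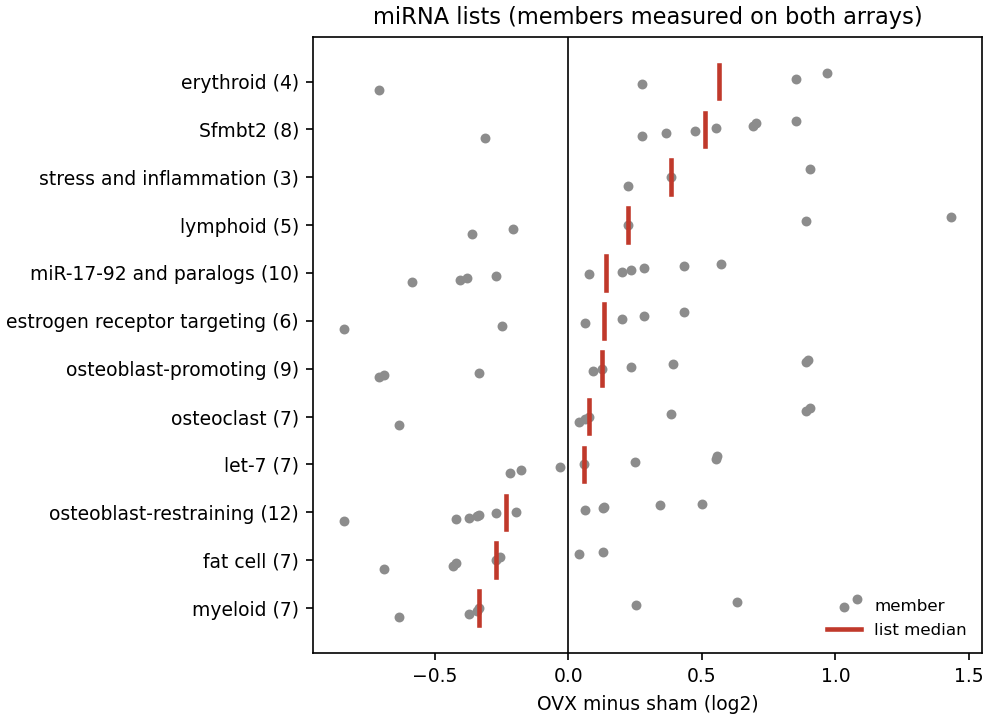
Log2 OVX minus sham (x axis) of the measured members (grey points) of the 12 fixed lists with at least 3 of them, 1 row per list with the number measured in brackets; red bars are list medians. The medians run from -0.33 for the myeloid list to 0.56 for the erythroid list, and members of most lists lie on both sides of 0. When the arrays are not scaled all list medians lie above 0, as does the median of all miRNAs (0.97).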

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

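All tests here were chosen after the result was seen. Control probes, which the comparison does not use, were brighter on the OVX array: the median log2 OVX minus sham over the 10 control probes well above background on both arrays was 0.38, a factor of 1.30, with a range of 0.12 to 0.80.

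The miRNAs were brighter still. Before scaling, their median difference was 0.97 (95% bootstrap interval over miRNAs 0.83 to 1.08), and 121 of the 197 lay above the highest control. A brighter hybridisation or scan of the whole array would raise the controls as much. The highest control, at 0.80, lay just below the interval's lower end of 0.83, and the rest lay at or below 0.64. That control was also the dimmest, with a signal of 164.7 on the sham array. The controls therefore do not exclude a brighter array. More efficient labelling would raise the spike-ins added before labelling as much, and these averaged 0.38, against 0.12 for the spike-ins added at hybridisation. A gain of 0.59 beyond the labelling spike-ins stays open. It may come from more miRNA in the RNA put on the OVX array, through its amount, its quality or an effect of ovariectomy. With 1 pool per group these cannot be told apart from each other or from a brighter array.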

How the results depend on the processing

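The alternatives that scale to control probes, correct for GC, leave out departing gene signals or keep the value table's printed names, and all alternatives for the bounds, were chosen after seeing the data. The counts of 4 higher and 4 lower at 2-fold depend on the scaling, which moves all values together: the median of all miRNAs moved by 0.15 with the 75th percentile of all probes, by -0.18 with the median, by 1.01 without scaling and by 0.64 with control-probe scaling. The higher counts were then 12, 2, 97 and 40. The lower counts were 12 with the median, 8 with quantile normalization, 0 without scaling and 0 with control-probe scaling. Normexp, which adds an offset of 50 to each signal and so draws dim differences towards 0, gave 0 and 0 and a spread of 0.35. The sum of probes gave 2 and 8, GC correction 2 higher, and the 1.5-fold threshold 22 and 29. No miRNA above the median level was 2-fold lower (0). With all miRNAs floored the spread was 0.32. The gene-level signal gave 24 and 28 and a spread of 1.12, over 281 miRNAs. Without the miRNAs whose gene signal departs from their probes it gave 17 and 2 and a spread of 0.53, over 186 miRNAs. In the first, 8 of the 10 named as higher stayed above 0, and in the second all 8 of those it measured did. The value table gave 10 and 43 and a spread of 1.07 with names moved by 1 row, and 10 and 43 and 1.07 with names as printed. It was compared over 281 and 282 miRNAs. The counts from the gene-level signal and the value table therefore cover other sets than the 197 miRNAs compared as reported. They do not show the effect of the signal alone. Under the printed names miR-5121 was at -3.03 and miR-26b-5p at -0.40. Requiring all probes, 133 miRNAs were present on the sham array; by Agilent's detection call 10 were on the sham array only. Except where the construction is named, the cause was not tested. The medians of 9 of the 12 lists were above 0 as reported, and of 9 with quantile normalization, 4 with median scaling and 8 with normexp. The count was 12 without scaling, 12 with control-probe scaling and 0 with all miRNAs floored. The 0 follows from the unequal floors of the arrays, which put the median of all miRNAs at -0.90 in that setting. Relative to the median of all miRNAs, 0 lists changed side under these scalings or normexp, 2 when floored and 2 among miRNAs above the median level. With the printed names 3 of 10 changed side. The number was 1 each with the gene-level signal, the gene-level signal without departing miRNAs, the value table with names moved and GC correction. Of the 84 named miRNAs measured on both arrays, 3 changed sign with the 75th percentile of all probes, 10 with median scaling, 4 with quantile normalization, 37 without scaling, 27 with control-probe scaling, 20 with the gene-level signal and 14 with normexp. Without scaling the log2 bounds of miR-3095-3p and miR-6944-5p were -0.11 and -0.13. Signal over background limits what has a value, as 1577 miRNAs were well above background on neither array; how many of the 102 present on the OVX array only have a fold depends on the scaling (22 as reported, 81 with control-probe scaling and 102 without scaling). Groups of 1 sample allow no leave-one-out, and no paired analysis was possible because each group holds 1 sample.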

Other observations

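The tests and the correction for probe GC content described here were all chosen after the results were seen. With the linear trend with GC removed, the list of rodent repeat miRNAs had a median of 0.38 (percentile 97.9), the stress and inflammation list 0.35 (percentile 96.1) and the osteoblast-restraining list -0.19 (percentile 6.7). The red-cell median went from 0.56 to 0.32 (percentile 89.2), and the let-7 median from 0.06 to -0.17 (percentile 35.8).

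The differences followed the base composition of the probes: Spearman's rho with GC content was -0.32 across the 197 miRNAs (95% bootstrap interval over miRNAs, which are not independent replicates, -0.45 to -0.18). The 29 miRNAs with probes under 40% GC had a median difference of 0.55, and the 73 above 60% had one of -0.19. Dim probes near background would leave no such trend among bright miRNAs, but rho was -0.40 in the 99 at or above the median level. Hybridisation stringency stays open: the median difference between a miRNA's longer and shorter probe was 0.0321 within 139 miRNAs, with 57 below 0, but the probes differ by a median of 1 base and the effect of 1 base was not tested; the stringency spike-in ratio was 1.28 on the sham array and 1.33 on the OVX array. An effect of ovariectomy on low-GC miRNAs and a bias of labelling or extraction with base composition were not tested.

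The red-cell miRNAs differed in opposite directions, with miR-144-5p at 0.97 and miR-486a-5p at -0.71. Without scaling they did not, as miR-486a-5p was at 0.31. With a gene-level signal that departed from its probes, miR-144-5p was at -1.29. The differences of the red-cell miRNAs spanned 1.68. With 1 array per group this range has only noise between probes to be set against, so a larger or smaller share of red-cell RNA stays open. Probe GC content may account for part of the gap, as the range was 1.17 after the trend was removed, and the test could not tell. miR-486a-5p is also found in muscle. The muscle miRNAs miR-133b-3p and miR-133a-3p were present on the sham array only, with bounds of 2.80-fold and 2.04-fold. Both were dim with 1 of 2 probes present, and without scaling the bounds were 1.39-fold and 1.01-fold. miR-1a-3p was not well above background on either array. A difference in the share of muscle RNA and an effect of ovariectomy on red-cell precursors were not tested.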
